A study of Drosophila melanogaster with 51 samples.

How the data were processed

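The series holds 51 samples of Drosophila intestinal cell types, in which Dam alone or Dam fused to a chromatin protein was expressed with a cell type driver. Files of 15 Dam-only samples were used: 3 of EC, 7 of EB and 5 of EE. The other 36 samples, with Dam fused to RNA polymerase II, Polycomb, HP1, H1 or Brm, were not analysed here. Per the labels' protocols, each replicate came from 60 guts, flies were reared at 18 °C and moved to 29 °C for 24 h when 3 days old, and DNA cut by DpnI at methylated GATC was ligated to adaptors, digested with DpnII, amplified by PCR, sonicated and freed of adaptors with AlwI. The labels do not state whether replicates are separate sets of animals beyond the pools of guts, nor the sex of the flies.

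The deposited files give a signal for each GATC fragment: mean binned read coverage divided by 1 factor per library, so that all libraries sum to nearly the same total. This reading rests on the values, since the files have no header and the labels name no step after sequencing. In fragments of up to 20 bp, 100% of values were whole multiples of 1 step per library (tolerance 0.001 of a step). All files hold the same fragments, with a median length of 197 bp and a longest of 54283 bp, and 0 pairs of libraries were identical. The step gave the summed coverage behind each library, 24.08 to 123.92 M (mega-units), which limits the precision of low values. PCR reads are not independent molecules, so this depth covers counting error alone, and no count test was applied.

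The genome build and the aligner are not given in the sources used here. The fragment coordinates reach the chromosome extents of Release 6. The mean signal at gene ends was 3.40 at the annotated positions, 3.43 and 3.51 with the annotation moved by 1000 bp down or up, and 2.48 with it moved by 50000 bp in either direction, so an offset of that smaller size is not excluded. Gene names and extents came from the gene table of the assembly Release 6 plus ISO1 MT, and coordinates printed are those of the fragments in the files. That table gives neither strand nor exons, so the planned windows around the 5′ end could not be made. The gene body, which had been set as the other choice of window, took their place: the value of a gene is the length-weighted mean signal of fragments over its body. "Outside genes" means outside annotated protein-coding genes.

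Libraries were scaled to an equal mean over the 5 large chromosome arms, and values were taken as log2(signal + 0.5), a pseudocount set from the median of non-zero fragment values, 1.01. Features with a mean of at least 0.2 times the genome-wide median were tested: 12509 of 13911 protein-coding genes (median 2.81, floor 0.562) and 289249 fragments (median 1.09, floor 0.217). The 3 groups were fitted in 1 model of all 15 libraries with limma 3.58.1 (lmFit, eBayes with trend and robust) in R 4.3.3, so that they share 1 estimate of the spread. Calls have a Benjamini-Hochberg adjusted p under 0.05, per comparison and two-sided. Adjacent called fragments of 1 direction with a gap of at most 1 fragment were joined into regions. The comparisons were EC against EB, EE against EB and EC against EE, and a log2 fold change is the first group less the second.

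For each of 17 gene lists (EC digestive enzymes, EC structure and transport, EE hormones, EE secretory machinery, EE transcription factors, stem cell and EB genes, the Notch target complex, midgut regional transcription factors, ribosomal proteins, cell cycle and DNA replication, immune effectors, homeobox and patterning genes, neurons, glia, trachea, visceral muscle, and haemocytes and fat body) limma's camera compared members with all other genes, with a preset correlation of 0.01, adjusted over 51 tests, and again with an estimated correlation. Of the entries, 451 matched by symbol, 7 by synonym and 92 by symbol prefix, and 11 were not used here. Lists share members: nub stands in 3 of them. The named genes are, per comparison, the 10 highest and the 10 lowest log2 fold changes among called genes with a symbol other than a CG or CR number whose groups do not overlap, the stronger of overlapping genes being kept, from which the text takes examples. Members of each list with the largest changes, fixed cell type markers and the 3 regions per direction with the lowest adjusted p were added.

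The comparisons, lists, naming rule, thresholds and most alternatives were chosen before the data were examined. 26 alternatives were added afterwards: a length-adjusted signal, in which each library's mean in each of 40 bins of fragment length was set to the mean over libraries, EB replicates 1 to 3 left out, these together, and other windows around genes. Replicate numbers did not pair the libraries, and run codes, read from file names, served as blocks in alternatives. Correlations of fold changes against the shared EB libraries were set beside 100 simulations of unchanged groups.

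The scripts were tested on simulated data with 200 changed features. Among genes, 39% of changes of log2 1 and 87% of changes of log2 2 were recovered in EC against EB, and 36% and 85% in EC against EE. Among fragments the shares were 3% and 34% in EC against EB, and 0% and 26% in EC against EE. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and the R package data.table, version 1.17.8, did the remaining steps.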

Results

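Chromatin accessibility was compared between cell types of the adult Drosophila intestine with Dam-only profiles. Intestinal stem cells renew this epithelium. Enteroblasts (EB) are the progenitors that become absorptive enterocytes (EC), and enteroendocrine cells (EE) are the hormone-secreting cells of the same epithelium. Untethered Dam, a bacterial methylase of adenine in the sequence GATC, was expressed under a driver of each cell type, and methylated GATC fragments were amplified from dissected guts. Free Dam methylates open chromatin more than closed chromatin, so the signal of a GATC fragment is read as accessibility in the cells that express the driver. The series has no sample of the DNA amount itself, so the signal was not corrected for DNA copy number. The profiles were made with MyoIA-Gal4 for EC, with a Notch-responsive driver for EB and with pros-Gal4 for EE. Each replicate pooled 60 guts, and Dam was induced for 24 h at 29 °C after rearing at 18 °C.

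The data comprised 15 Dam-only libraries: 3 of EC, 7 of EB and 5 of EE. Each gave a signal for the same GATC fragments. The coverage summed over fragments, in mega-units (M), was 68.12 to 85.98 M in the EC libraries and 67.08 to 107.92 M in the EE libraries. It was 24.08, 26.26 and 35.2 M in EB replicates 1 to 3 and 49.64 to 123.92 M in EB replicates 4 to 7. The signal of a gene is the mean Dam signal over its body, and fold changes are on the scale of log2(signal + 0.5), which understates changes of low genes. The labels give pools of guts and no further origin, so p-values measure the spread between these samples, part of which may be technical.

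EB replicates 1 to 3 stood apart from all other libraries. The codes in their file names, read here as run codes, were shared with no library outside these 3. That also held for libraries that did not stand apart, such as EB replicate 5 and EE replicate 1. Below, early and later name EB replicates 1 to 3 and 4 to 7, without known dates. No run code held EB together with another group. For EB the batch and the group therefore cannot be told apart. Fragments of 500 to 1500 bp held 32.9% ± 3.30 of the signal in EB replicates 1 to 3 (SD, n = 3), against 9.03% ± 3.52 in EB replicates 4 to 7 (n = 4), 8.42% ± 4.26 in EC (n = 3) and 9.0% ± 2.0 in EE (n = 5). Fragments of 150 to 400 bp held 27.4% ± 2.88 and 51.3% ± 3.37 of the signal in the early and later EB libraries. Across genes, which are not independent replicates, the median Pearson correlation between an early and a later EB library was 0.611. With both EB subsets pooled, the median was 0.776 between EB and EE libraries and 0.71 between EB and EC libraries. Early EB libraries alone correlated at 0.369 to 0.595 with EE and at 0.428 to 0.631 with EC libraries. The median was 0.926 among EB replicates 4 to 7, 0.909 among EC and 0.929 among EE libraries. Each library's signal was also set to a common profile over 40 bins of fragment length, an adjustment chosen after these values were seen. The median correlation was then 0.812 between early and later EB, 0.819 between EB and EE, and 0.763 between EB and EC libraries. The counts of called genes and fragments against EB are therefore also given without EB replicates 1 to 3.

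**Figure D1:**
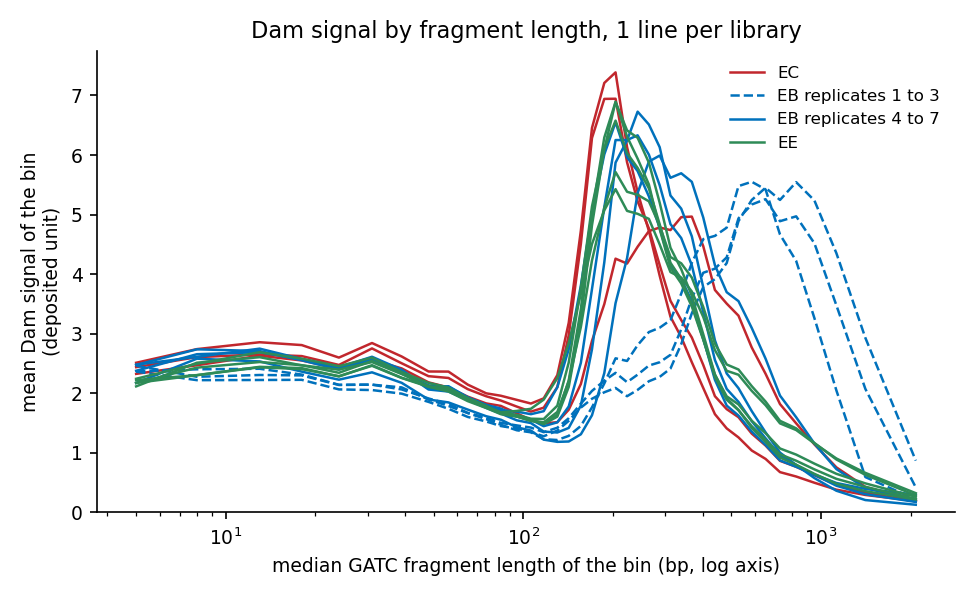
Mean Dam signal (deposited unit) of GATC fragments in 40 bins of fragment length (bp, log axis), 1 line per library. The 3 dashed lines of EB replicates 1 to 3 peak above 500 bp, while the other 12 libraries peak between 150 and 400 bp.

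In EC against EB, digestive enzyme genes gained Dam signal, and the progenitor genes esg, Sox21a and N lost it. As a list, stem cell and EB genes lost their call with an estimated correlation between genes (adjusted p = 0.559), with the length-adjusted signal (0.0817) and with centring on 100 kb windows. Bace, an aspartic protease gene, stood at a signal of 10.6 ± 3.18 in EC (SD, n = 3) and 0.602 ± 0.302 in EB (n = 7), a log2 fold change of 3.33 ± 0.25 (SE, adjusted p = 2.54e-07). The trypsin gene epsilonTry rose by 2.97 ± 0.36 and the alpha-mannosidase gene LManIV by 2.97 ± 0.22. In the other direction esg, the Snail-family factor that maintains progenitors, stood at 1.24 ± 0.203 in EC and 7.32 ± 2.14 in EB, a change of -2.12 ± 0.26 (adjusted p = 2.09e-05). The progenitor factor gene Sox21a changed by -2.38 ± 0.29 and N, which encodes the Notch receptor, by -2.08 ± 0.19. Of 12509 genes tested, 1422 were higher and 2741 lower in EC.

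The 51 digestive enzyme genes, a list of trypsins, Jonah proteases, maltases, mannosidases and lysozymes, gave 39 higher and 1 lower. Adjusted over the list alone, 41 were higher and 1 lower. Their median shift, less the median of all genes, was 1.67 (camera, adjusted p = 1.09e-25), and the call held with an estimated correlation (adjusted p = 0.00250). The marker betaTry, a trypsin gene, changed by 2.28 ± 0.24. Among other genes with the largest gains were Srg2 (3.61 ± 0.44), Eglp1, which encodes an entomoglyceroporin (3.26 ± 0.33), wntD (3.18 ± 0.29), Cyp309a1, a cytochrome P450 gene (3.06 ± 0.23), Daao2, a D-amino acid oxidase gene (2.97 ± 0.20), the metallothionein gene MtnC (2.95 ± 0.41) and Vha100-5, which encodes a proton pump subunit (2.90 ± 0.24).

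Midgut regional transcription factors gave 9 higher and 2 lower of 23 (adjusted over the list alone, 9 and 2; shift 0.53, adjusted p = 0.00331, and adjusted p = 0.520 with an estimated correlation). Among them odd changed by 2.20 ± 0.30 and vnd by 1.53 ± 0.26. The list of EC structure and transport genes gave 13 higher and 9 lower of 39 (list alone, 13 and 10; shift 0.29, adjusted p = 0.0370, and adjusted p = 0.660 with an estimated correlation). In it the septate junction gene mesh changed by 1.81 ± 0.22 and the cadherin gene Cad96Ca by -1.83 ± 0.30. The nubbin gene nub, an enterocyte marker that stands in 3 of the lists, changed by 1.32 ± 0.18. Myo31DF, the gene of the EC driver, stood at 6.5 ± 0.811 in EC and 4.09 ± 1.58 in EB; its change of 0.67 ± 0.25 (adjusted p = 0.0476) was 1.06 without EB replicates 1 to 3 (adjusted p = 8.12e-05), lost its call without any of 12 of the 15 libraries and was -0.04 over windows of 1 kb around both gene ends. Ribosomal protein genes gave 12 higher and 5 lower of 89 (list alone, 11 and 4), with a median change of -0.04 that lay above that of all genes by 0.20 (adjusted p = 0.0472, and adjusted p = 0.665 with an estimated correlation).

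The list of stem cell and EB genes gave 1 higher and 14 lower of 32 (list alone, 2 and 15; shift -0.24, adjusted p = 0.0119, and adjusted p = 0.559 with an estimated correlation). The Notch target complex gave 1 higher and 6 lower of 13 (list alone, 1 and 6; shift -0.58, adjusted p = 0.0262, and adjusted p = 0.532 with an estimated correlation), with E(spl)mbeta-HLH at -2.41 ± 0.35 and E(spl)mdelta-HLH at -1.46 ± 0.24. The marker klu, a zinc finger gene of enteroblasts, differed by -0.26 ± 0.17 (adjusted p = 0.261). Cell cycle and replication genes gave 0 higher and 13 lower of 32 (list alone, 0 and 16; shift -0.30, adjusted p = 0.0472, and adjusted p = 0.558 with an estimated correlation and 0.0962 with the length-adjusted signal), with CycA, the cyclin A gene, at -1.26 ± 0.17.

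Lists of trachea, neurons and visceral muscle were also lower in EC. Tracheal genes gave 0 higher and 12 lower of 14 (list alone, 0 and 14; shift -1.22, adjusted p = 4.28e-07, and adjusted p = 0.520 with an estimated correlation). The FGF receptor gene btl changed by -1.74 ± 0.18, knrl by -2.36 ± 0.23 and pio by -2.20 ± 0.32. Neuronal genes gave 0 higher and 24 lower of 38 (list alone, 0 and 28; shift -0.36, adjusted p = 3.47e-05, and adjusted p = 0.559 with an estimated correlation), with ple, the tyrosine hydroxylase gene, at -2.48 ± 0.24 and elav at -1.18 ± 0.23. Visceral muscle genes gave 0 higher and 15 lower of 25 (list alone, 0 and 16; shift -0.45, adjusted p = 5.05e-04, and adjusted p = 0.520 with an estimated correlation), with how at -1.98 ± 0.24. Homeobox and patterning genes gave 0 higher and 20 lower of 41 (list alone, 0 and 21; shift -0.32, adjusted p = 1.96e-04, and adjusted p = 0.520 with an estimated correlation), with kni, which also stands in the tracheal list, at -2.37 ± 0.20. The largest losses included Npc2b, a gene of the NPC2 family of sterol-binding proteins (-3.41 ± 0.26), Nil (-3.39 ± 0.27), the TRP channel gene pain (-2.87 ± 0.15), spz, which encodes the Toll ligand Spätzle (-2.73 ± 0.22), and the ETS factor gene Ets98B (-2.74 ± 0.32).

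The lists of EE hormones (1 higher and 3 lower of 13, adjusted p = 0.305), EE secretory machinery (2 and 9 of 24, 0.0539), EE transcription factors (2 and 6 of 16, 0.207), haemocytes and fat body (0 and 9 of 22, 0.287), glia (0 and 3 of 9, 0.188) and immune effectors (3 and 4 of 27, 0.869) did not pass the test between EC and EB. Their counts adjusted over the list alone were 1 and 3, 2 and 10, 2 and 7, 1 and 9, 0 and 3, and 3 and 4. The median of the immune effectors, -0.18, lay above that of all genes. Single members that changed included the dual oxidase gene Duox (-1.96 ± 0.30), the ion transport peptide gene ITP (-1.45 ± 0.17, but 0.38 over windows around both gene ends) and Dh31, a diuretic hormone gene (1.16 ± 0.17). The marker genes tap (-0.37 ± 0.29), AstC (-0.28 ± 0.33), Tk (-0.39 ± 0.18) and Mhc (-0.28 ± 0.17) did not pass. Without EB replicates 1 to 3 tap passed (-0.76, adjusted p = 0.0166). Mhc passed in the other direction over windows around both gene ends (0.63, adjusted p = 0.0329). The change of pros, -0.48 ± 0.16 (adjusted p = 0.0311), lost its call without EC replicate 1 (adjusted p = 0.0545), EC replicate 2 (0.0728), EC replicate 3 (0.134) or EB replicate 1 (0.0535). It was 0.10 with centring on 100 kb windows (adjusted p = 0.828).

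Of the 2202 genes changed at least 2-fold between EC and EB, 724 were higher and 1478 lower in EC. In 24.9% of tested genes every library of EC lay above or below every library of EB, against 1.67% by chance. Over 289249 fragments tested, 24618 were higher and 36206 lower, and 3.83% of the higher against 22.0% of the lower fragments lay outside annotated protein-coding genes. Of all tested fragments 15.6% did. The median length was 127 bp for the higher and 316 bp for the lower fragments, against 206 bp for all tested. The region with the lowest p among those higher in EC spanned 3R 25502592 to 25508179, near the ends of CG5107 and CG5111 (15 called fragments, mean log2 fold change 2.17), and single fragments inside CG34417 (X 6570604 to 6570894) and Gss1, a glutathione synthetase gene (X 17896084 to 17896421), followed. Lower regions lay inside Mnr (X 21270243 to 21277455), outside genes at 3L 20661716 to 20668202 and inside Tie, a receptor tyrosine kinase gene (3L 4521743 to 4529945).

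The split between gains and losses depended on how the signal was scaled and filtered. The median change of all genes was -0.24 and became -0.02 with quantile normalization, where 1444 genes were higher and 1618 lower, and -0.00488 with centring on 100 kb windows (1816 and 1843). Gains outnumbered losses among genes with the length-adjusted signal (3274 and 2832), with it and without EB replicates 1 to 3 (3396 and 2998), and with a filter at the genome-wide median (1008 and 863). Among fragments the higher share of 40.5% became 55.6% with quantile normalization (29690 higher and 23687 lower), 68.0% with equal medians (39660 and 18705) and 62.5% with centring (29768 and 17895). Without EB replicates 1 to 3, 1982 genes were higher and 2673 lower, as were 24837 and 47266 fragments, and the counts were 2646 genes and 24681 fragments without EC replicate 2 and 2595 genes and 23414 fragments without EC replicate 3. Centring on 100 kb windows, which removes any difference shared by a window, ended the calls of Srg2 (1.35, adjusted p = 0.0780), Nil (-0.41, 0.172) and esg (-0.47, 0.130). It subtracts the median of the tested genes of a window, the gene itself included. Where a window holds few tested genes, a change is therefore lost by construction. The genes kni (-0.0015) and knrl (0.0015) also lost their calls, with the mirrored values that a window holding them alone would give. Centring also ended the calls of the lists of stem cell and EB genes, Notch targets, EC structure and transport, visceral muscle, homeobox genes, cell cycle genes and ribosomal proteins, the last 3 of which quantile normalization ended too. List members that share a window lose their common shift by construction, so centring cannot weigh lists of clustered genes.

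In EE against EB, Tk and dimm gained signal over the gene body, and N and klu lost it. The lists of secretory machinery, trachea, and stem cell and EB genes shifted in these directions, but none of them passed with an estimated correlation between genes (adjusted p = 0.520 each). Tk, a tachykinin gene of enteroendocrine cells, stood at 3.25 ± 0.383 in EE (SD, n = 5) and 0.955 ± 0.244 in EB (n = 7), a log2 fold change of 1.38 ± 0.15 (SE, adjusted p = 3.18e-05). The proneural factor gene tap rose by 1.46 ± 0.25, dimm, a factor gene of peptide-secreting cells, by 1.37 ± 0.19, and the synaptotagmin genes Sytalpha and Sytbeta by 1.23 ± 0.17 and 1.28 ± 0.14. The Notch receptor gene N changed by -1.28 ± 0.16 and klu by -1.10 ± 0.15. Of 12509 genes, 1646 were higher and 1295 lower in EE.

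The EE secretory machinery gave 11 higher and 0 lower of 24 (list alone, 13 and 0; shift 0.66, adjusted p = 2.58e-05, and adjusted p = 0.520 with an estimated correlation), with Rab3 at 1.25 ± 0.20 and Rim at 1.06 ± 0.16. EE transcription factors gave 7 higher and 1 lower of 16 (list alone, 7 and 2; shift 0.29, adjusted p = 0.0371, and adjusted p = 0.537 with an estimated correlation). The driver gene pros stood at 1.82 ± 0.452 in EE and 0.573 ± 0.101 in EB, a change of 1.10 ± 0.14 (adjusted p = 8.84e-05), which was -0.50 after centring on 100 kb windows (adjusted p = 0.127) and -0.28 over windows around both gene ends. Over those windows Tk (0.06, adjusted p = 0.902), Rab3 (0.19, 0.724), Sytalpha (0.22, 0.316) and Sytbeta (-0.35, 0.521) also lost their calls. EE hormones gave 4 higher and 0 lower of 13 (list alone, 6 and 1) and did not pass as a list (shift 0.47, adjusted p = 0.106). AstA changed by 1.05 ± 0.17. AstC changed by 0.88 ± 0.28 (adjusted p = 0.0304), a call lost without EE replicate 1 (adjusted p = 0.0754), EE replicate 3 (0.0761) or EE replicate 4 (0.0708), while the length-adjusted change was 1.40 (adjusted p = 2.9e-06).

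Digestive enzyme genes were also higher in EE than in EB, with 19 higher and 0 lower of 51 (list alone, 26 and 1; shift 0.56, adjusted p = 9.64e-07, and adjusted p = 0.186 with an estimated correlation). LysD, a lysozyme gene, changed by 2.29 ± 0.55 (1.19 without EB replicates 1 to 3, adjusted p = 0.00356), the maltase gene Mal-A2 by 1.88 ± 0.30 and betaTry by 1.02 ± 0.20. Haemocyte and fat body genes gave 6 higher and 1 lower of 22 (list alone, 7 and 1; shift 0.33, adjusted p = 0.00724, and adjusted p = 0.520 with an estimated correlation), with the fat body gene Fbp2 at 1.12 ± 0.23 and the collagen IV gene Col4a1 at 1.00 ± 0.16. Without EB replicates 1 to 3 this list did not pass (adjusted p = 0.0654). The largest gains were those of gNacalpha (2.40 ± 0.23), EAChm (2.33 ± 0.16) and Ect3, a beta-galactosidase gene (2.30 ± 0.17).

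Tracheal genes were again lower, with 1 higher and 8 lower of 14 (list alone, 1 and 8; shift -0.75, adjusted p = 0.00108, and adjusted p = 0.520 with an estimated correlation), knrl at -1.67 ± 0.20 and btl at -1.07 ± 0.15. Stem cell and EB genes gave 1 higher and 13 lower of 32 (list alone, 2 and 15; shift -0.37, adjusted p = 5.54e-04, and adjusted p = 0.520 with an estimated correlation). Within that list Egfr changed by -0.93 ± 0.17, esg differed by -0.55 ± 0.22 without passing (adjusted p = 0.0801), and the change of Sox21a, -0.72 ± 0.25 (adjusted p = 0.0456), lost its call without EB replicates 1 to 3 (-0.40, adjusted p = 0.225) and without any of 12 of the 15 libraries. Ribosomal protein genes gave 2 higher and 12 lower of 89 (list alone, 1 and 8; shift -0.43, adjusted p = 5.09e-04, and adjusted p = 0.530 with an estimated correlation), RpL15 among them at -1.33 ± 0.35 (-0.70 without EB replicates 1 to 3, adjusted p = 0.0442, and 0 with centring on 100 kb windows). That 0 is what a gene equal to the median of its own window gets by construction. The largest losses were those of Irk2, a potassium channel gene (-2.26 ± 0.30), hui (-2.24 ± 0.33), snu, an ABC transporter gene of the cuticle barrier (-2.19 ± 0.33), fj, a Golgi kinase gene (-2.17 ± 0.22), Ser, which encodes a Notch ligand (-2.06 ± 0.21), and byn, the hindgut Brachyury homologue (-1.97 ± 0.29).

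The Notch target complex (0 higher and 3 lower of 13, adjusted p = 0.0775), neuronal genes (7 and 3 of 38, 0.357), homeobox and patterning genes (4 and 3 of 41, 0.798), visceral muscle (4 and 4 of 25, 0.951), EC structure and transport (7 and 1 of 39, 0.287), midgut regional factors (6 and 2 of 23, 0.156), cell cycle genes (2 and 2 of 32, 0.319), glia (1 and 3 of 9, 0.241) and immune effectors (5 and 5 of 27, 0.636) did not pass between EE and EB. Adjusted over the list alone they gave 0 and 3, 7 and 3, 4 and 3, 4 and 4, 7 and 1, 7 and 2, 2 and 2, 1 and 4, and 5 and 5. The medians of the homeobox list (-0.01) and the visceral muscle list (-0.05) lay above that of all genes. Without EB replicates 1 to 3, neuronal genes (adjusted p = 0.0212) and the Notch target complex (7.26e-06) passed. Both also passed with the length-adjusted signal (adjusted p = 0.0108 and 0.00390), as did EE hormones (0.00726). The markers nub (-0.17 ± 0.15), Myo31DF (-0.51 ± 0.21) and elav (-0.28 ± 0.19) did not pass, and Mhc, the muscle myosin gene, changed by 0.41 ± 0.14 (adjusted p = 0.0452), a call lost without any of 13 of the 15 libraries.

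At least 2-fold changes between EE and EB comprised 489 gains and 410 losses. In 14.1% of genes the libraries of the groups did not overlap, against 0.253% by chance. Among fragments 51278 were higher and 15632 lower in EE, and 15.5% and 15% of them lay outside genes. Their median lengths were 163 and 353 bp. The top gained regions spanned 2R 5049271 to 5053002 outside genes (9 called fragments, mean log2 fold change 2.94), 2L 8623413 to 8623837 inside Sema1a, a semaphorin gene, and 2R 21255823 to 21257673 near an end of Rgk3. Lower regions lay inside Hers (X 19898069 to 19898510), the homeobox gene otp (2R 20896754 to 20901843) and Cip4 (3L 4335874 to 4336243).

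The share of fragments higher in EE, 76.6%, became 52.3% with quantile normalization (38267 higher and 34883 lower), 44.5% with equal medians (28550 and 35659) and 47.6% with centring on 100 kb windows (26537 and 29228). Among genes the share of 56.0% became 48.9% (2060 and 2154), 47.4% (1750 and 1945) and 48.9% (1459 and 1522), and 42.1% with gene bodies and 1 kb each side (1200 and 1648). It was 39.8% with a filter at the genome-wide median (627 and 950), 48.1% without EB replicate 7 (1814 and 1955), 44.0% over windows around both gene ends (1031 and 1312), 38.1% with the replicate number as a block (2285 and 3713) and 67.5% with the length-adjusted signal (3392 and 1630). Centring ended the calls of klu (-0.10, adjusted p = 0.660), knrl (-0.12, 0.375), the tracheal list (shift -0.08, 0.229) and the EE transcription factors. For knrl, and for tracheal genes that share a window, part of that loss is fixed by the centring itself. Quantile normalization ended the calls of the EE transcription factors and of haemocytes and fat body. Without EB replicates 1 to 3, 2070 genes were higher and 1025 lower, as were 40697 and 13936 fragments, and fragments gave 43466 calls without EE replicate 2. With EB represented by replicate 7 alone, 360 genes were called.

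**Figure D2:**
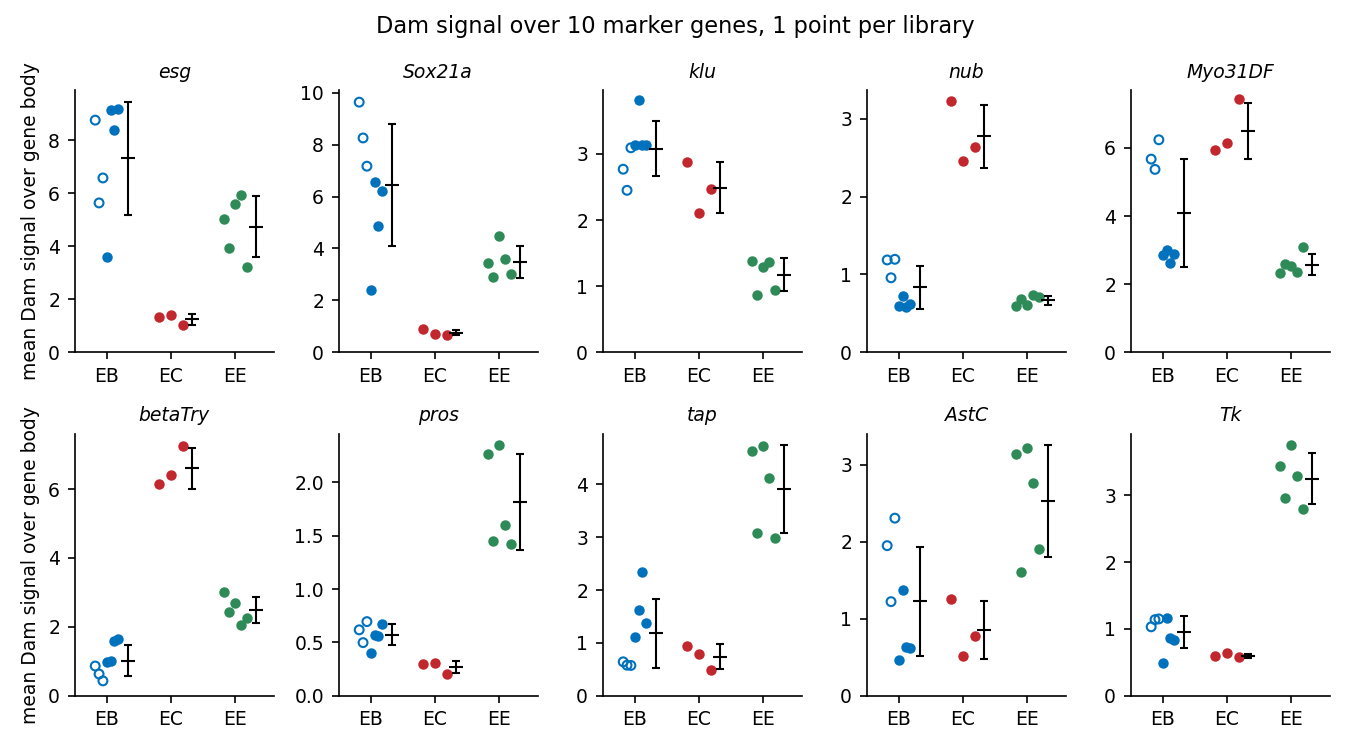
Mean Dam signal over the gene body (deposited unit) of 10 marker genes in EB, EC and EE, 1 point per library, with open circles for EB replicates 1 to 3 and bars for the group mean ± SD. The 5 EE points of Tk, tap and pros lie above all other points of these genes, and the 3 EC points of nub and betaTry lie above all others of theirs.

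In EC against EE, digestive enzyme genes were higher in EC, a list call that held with an estimated correlation between genes (adjusted p = 0.0116). The lists of secretory machinery, neuronal and hormone genes were higher in EE, but did not pass in that test (adjusted p = 0.520, 0.530 and 0.577). That test takes its correlation from all libraries, so the batch of EB replicates 1 to 3 enters it here too. LManIV stood at 9.29 ± 3.16 in EC (SD, n = 3) and 1.06 ± 0.223 in EE (n = 5), a log2 fold change of 2.6 ± 0.23 (SE, adjusted p = 7.62e-06). The marker betaTry changed by 1.26 ± 0.25, nub by 1.49 ± 0.19 and klu by 0.85 ± 0.18. Tk changed by -1.76 ± 0.19, tap by -1.83 ± 0.31, and the calcium channel gene cac by -1.88 ± 0.22. Of 12509 genes, 927 were higher and 2537 lower in EC.

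Digestive enzyme genes gave 29 higher and 1 lower of 51 (list alone, 34 and 2; shift 1.16, adjusted p = 9.76e-16), and this call held with an estimated correlation (adjusted p = 0.0116). Ribosomal protein genes gave 14 higher and 4 lower of 89 (list alone, 14 and 3; shift 0.55, adjusted p = 7.22e-07, and adjusted p = 0.520 with an estimated correlation), with RpLP2 at 2.98 ± 0.54. Midgut regional factors gave 6 higher and 4 lower of 23 (list alone, 7 and 4; shift 0.30, adjusted p = 0.0432, and adjusted p = 0.520 with an estimated correlation), with odd at 2.35 ± 0.32, and did not pass when EB replicates 1 to 3 were left out of the shared fit (adjusted p = 0.0612). Further large gains were those of Daao2 (2.55 ± 0.21), Phae2, a serine protease gene (2.35 ± 0.22), and Mal-A7, a maltase gene (2.04 ± 0.32).

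The EE secretory machinery gave 0 higher and 16 lower of 24 in EC (list alone, 0 and 16; shift -1.04, adjusted p = 4.28e-06, and adjusted p = 0.520 with an estimated correlation), with Sytalpha at -1.86 ± 0.21 and brp, an active zone gene, at -1.64 ± 0.19. EE transcription factors gave 0 and 10 of 16 (list alone, 0 and 10; shift -0.79, adjusted p = 0.00302, and adjusted p = 0.520 with an estimated correlation), with dimm at -1.83 ± 0.24. EE hormones gave 1 and 7 of 13 (list alone, 1 and 8; shift -0.88, adjusted p = 0.0359, and adjusted p = 0.577 with an estimated correlation), with AstA at -1.5 ± 0.21. Neuronal genes gave 0 and 21 of 38 (list alone, 0 and 25; shift -0.53, adjusted p = 7.22e-07, and adjusted p = 0.530 with an estimated correlation), with ple at -1.66 ± 0.26.

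Other lists lower in EC than in EE were homeobox and patterning genes (0 and 18 of 41, list alone 0 and 23, shift -0.49, adjusted p = 2.68e-05), visceral muscle (0 and 16 of 25, list alone 0 and 17, -0.63, 1.46e-04), trachea (0 and 9 of 14, list alone 0 and 11, -0.71, 2.55e-04) and haemocytes and fat body (0 and 14 of 22, list alone 0 and 16, -0.71, 0.00112). For each of these 4 lists the adjusted p was 0.520 with an estimated correlation, and with quantile normalization the homeobox shift was 0.04 (adjusted p = 0.729). Members included the homeobox gene H2.0 (-1.55 ± 0.29), the myosin light chain gene Mlc1 (-1.5 ± 0.28), the chitin deacetylase gene verm (-1.36 ± 0.21) and Col4a1 (-1.57 ± 0.20). The markers esg (-1.56 ± 0.28), Sox21a (-1.66 ± 0.31), elav (-0.90 ± 0.24) and Mhc (-0.69 ± 0.18, but 0.16 over windows around both gene ends, adjusted p = 0.696) were lower in EC, as were btl (-0.68 ± 0.19) and AstC (-1.16 ± 0.34), whose calls were lost without EC replicate 2 or EC replicate 3. The driver genes pros and Myo31DF changed by -1.58 ± 0.17 and 1.19 ± 0.26, and centring on 100 kb windows put pros at 0.60 (adjusted p = 0.169), esg at -0.23 (0.550) and Sox21a at -0.39 (0.559). It also ended the list calls of EE hormones, EE transcription factors, haemocytes and fat body, homeobox genes and visceral muscle, and quantile normalization those of homeobox genes, trachea and haemocytes and fat body. The largest losses were those of gNacalpha (-2.83 ± 0.29), nol (-2.66 ± 0.56), EAChm (-2.50 ± 0.20) and the gustatory receptor gene Gr36a (-2.38 ± 0.28).

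Stem cell and EB genes (5 higher and 11 lower of 32, adjusted p = 0.773), the Notch target complex (0 and 4 of 13, 0.207), cell cycle genes (0 and 6 of 32, 0.167), EC structure and transport (10 and 10 of 39, 0.116), glia (0 and 3 of 9, 0.508) and immune effectors (2 and 3 of 27, 0.636) did not pass between EC and EE. Adjusted over the list alone they gave 5 and 11, 0 and 4, 0 and 6, 13 and 12, 0 and 3, and 2 and 3. The median of the immune effectors, -0.04, lay above that of all genes.

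**Figure D3:**
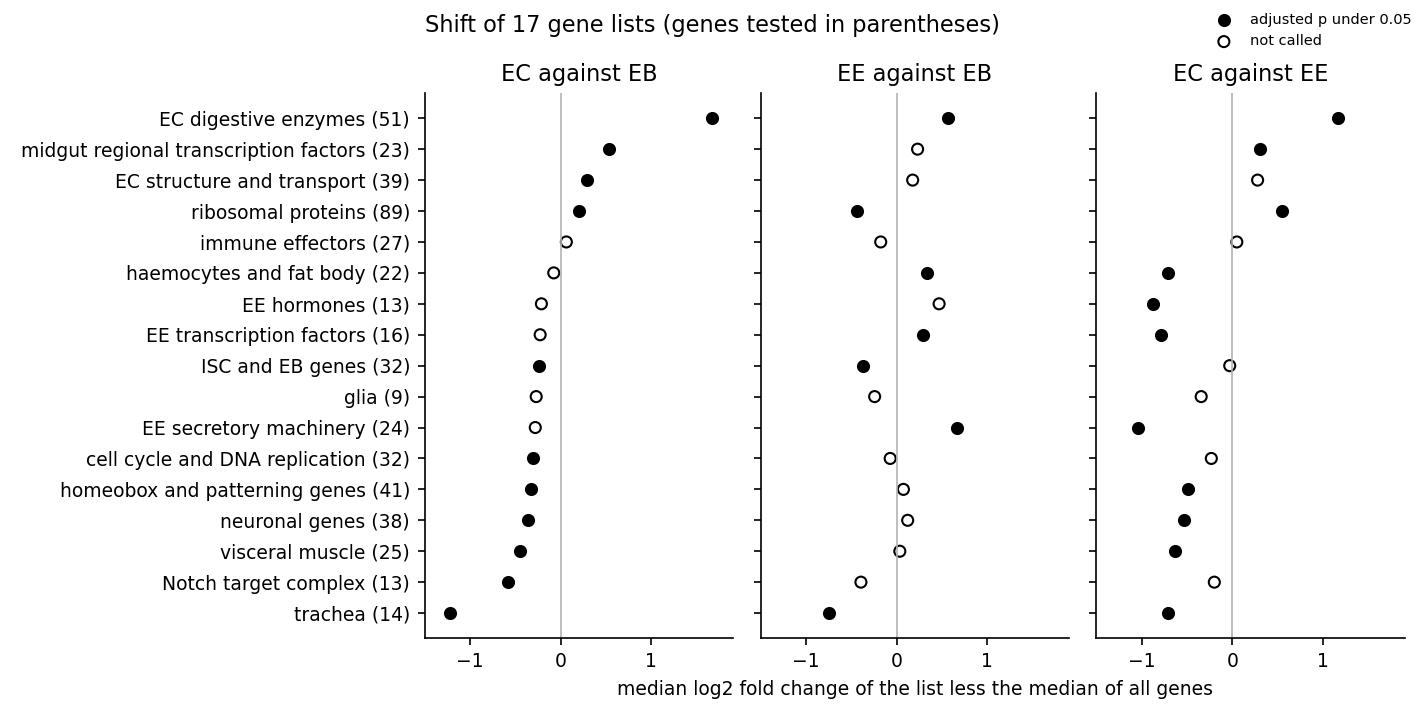
Median log2 fold change of each of the 17 gene lists less the median of all genes, in 3 panels for the comparisons, 1 point per list, filled where the preset-correlation test passed. Digestive enzymes lie at 1.67, 0.56 and 1.16, and tracheal genes at -1.22, -0.75 and -0.71; with an estimated correlation the digestive enzymes alone passed, in EC against EB and EC against EE.

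At least 2-fold changes between EC and EE comprised 368 gains and 1280 losses, and in 43.2% of genes the libraries of the groups did not overlap, against 3.57% by chance. Among fragments 5526 were higher and 40284 lower in EC, and 3.73% and 22.8% of them lay outside genes. Their median lengths were 114 and 231 bp. The top regions lower in EC lay outside genes at 3L 19862238 to 19863024 and 3L 23118496 to 23119409 and inside Sema1a at 2L 8623413 to 8624855, while Gss1, CG5107 with CG5111 and CG34417 again held the top gained regions. Pairs of EC and EE libraries shared 2 run codes. Within those 4 libraries, with the run code as a block, 2718 genes were called, 828 higher and 1890 lower. Among fragments the higher share of 12.1% became 49.4% with quantile normalization (12304 and 12623), 68.3% with equal medians (17259 and 8018) and 59.9% with centring (10881 and 7286). Among genes the share of 26.8% became 46.5% (849 and 975), 42.5% (1661 and 2246) and 48.1% (1253 and 1351). It was 58.5% with a filter at the genome-wide median (585 and 415) and 41.7% with the length-adjusted signal (2542 and 3561). Without EC replicate 3 the count was 2266 genes, and fragment counts were 28920, 24518 and 20144 without EC replicates 1, 2 and 3.

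The shifts of EC and EE from EB shared direction across genes, which are not independent replicates, but no value of this overlap leaves out EB replicates 1 to 3. Their log2 fold changes correlated at 0.554, where unchanged groups against the same EB libraries gave 0.623 in 100 simulations. The covariance was 0.261 against a simulated 0.0499. The simulation drew the EB libraries as independent, while EB replicates 1 to 3 deviate together. Its covariance may therefore lie too low, and the excess does not separate a shared shift from that batch. With the EB libraries split so that each comparison had its own, the covariance was 0.227 and 0.225. Both parts held libraries of EB replicates 1 to 3, so that batch was still shared. In both comparisons 542 genes were higher, against 187 for independent lists, and 724 lower, against 284. Opposite calls numbered 13 for genes higher in EC and lower in EE, against 147, and 176 for the reverse, against 361. The independent-list figures leave out the shared EB libraries.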

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

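The tests of the 3 patterns weighed here were chosen after the results were seen; the counts over other splits of the libraries were planned.

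EB replicates 1 to 3 differed from EB replicates 4 to 7 in fragment length and correlated with them at 0.611 across genes. Lower depth alone is argued against, since sampling fewer reads keeps the expected share of 500 to 1500 bp fragments, and that share differed by 23.85 percentage points. Length as the whole difference is argued against as well: with the length-adjusted signal the highest early-later correlation was 0.8399, below the lowest of 0.927 among replicates 4 to 7. Selection of longer fragments in part of the difference stays open, with 28.92% of the variance of the difference held by 40 length bins. Other splits of the 7 libraries held a median of 25.4%, but they too part the early libraries unequally and so do not weigh against it. These replicates share no run code with other libraries, so a library batch may account for the rest, but some libraries that did not stand apart also have unshared codes. A difference in the genotype of the flies stays open too: mthl8 had a signal of 3.06, 2.03 and 3.57 in EB replicates 1 to 3 and 1.38 to 1.98 in EC, but at most 0.002 in EB replicates 4 to 7 and 0.0083 in EE. This single gene was picked after its values were seen and does not account for the difference across genes. The design gives no biological explanation that was tested.

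Tracheal genes were higher in EB than in EC and EE, a list call lost in both comparisons with an estimated correlation (adjusted p = 0.520 in each). With the preset correlation, length selection is argued against, since the list kept at least 0.81 of its shift with the length-adjusted signal, and EB replicates 1 to 3 alone are argued against, since without them the higher adjusted p was 0.0007738. Dam expressed in other cuticle-forming cells by the EB driver may contribute: cuticle protein and Osiris genes together, whose symbols define them, were lower in EC than in EB (less all genes -0.56, adjusted p = 1.21e-05, 0.195 with an estimated correlation and 0.362 with centring) but not in EE (0.02, adjusted p = 0.9721). The hindgut gene byn stood at 1.67 to 6.48 in the EB libraries, at most 0.77 in EC and at most 0.71 in EE, but it was picked from the largest losses. The values leave that source open, and with centring on 100 kb windows the tracheal shift in EE against EB was -0.08 (adjusted p = 0.229). Centring removes by construction the common shift of list members that share a window, so that value does not weigh on the source. A difference in the chromatin of enteroblasts themselves stays open and untested.

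Digestive enzyme genes were higher in EE than in EB, a list call lost with an estimated correlation (adjusted p = 0.186). Length selection is argued against, since 0.784 of the shift stayed with the length-adjusted signal. The batch of EB replicates 1 to 3 was not weighed here for this list, and the fractions below use the mean of all EB libraries. Mal-A2 stood at 0.63 to 0.83 in those replicates and at 1.82 to 3.42 in EB replicates 4 to 7. For LManIV the ranges overlapped, with 0.71 to 0.83 and 0.43 to 1.01. EC chromatin in the EE libraries would move other EC genes by the same fraction of their difference between EC and EB. That fraction had a median of 0.181 over 39 called enzyme genes (quartiles 0.0612 and 0.283) and 0.190 over 13 called structure and transport genes (quartiles -0.0652 and 0.348; two-sided permutation p = 1, 100000 resamples), so EC chromatin may be the source and cannot be told apart from open enzyme genes in EE cells themselves. For LysX the fraction was 1.79, and LysD, outside these sets, had a mean signal of 14.4 in EE and 9.67 in EC. Neither gene passed the test between EC and EE (adjusted p = 0.319 for LysX and 0.585 for LysD), which does not show that the groups are equal. The fraction was below 0 for 3 of the 39 enzyme genes, among them Mal-A6 (-0.27), and for 4 of the 13 structure and transport genes, among them Myo31DF (-0.63). A share of EC chromatin alone gives fractions from 0 to 1, but the error of single fractions was not tested, so these members do not settle the source.

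Under 5% of the drawn splits reached each count, which argues against chance, except for the fragments of EC against EB. There the share cannot decide, since the draw left out the split following EB replicates 1 to 3, which called more. In EC against EB and EE against EB the splits do not exclude the batch of those replicates. In EC against EB, 2 of 100 splits gave as many genes as the real 4163, and the highest other, 7393, took EB replicates 1 to 3 as the group of 3. That split follows the run codes and calls more genes than the real split, which points to the structure of the EB libraries, and without those replicates EC against EB gave 4655 genes. In EE against EB it was 1 of 100 (real 2941, highest other 2833, which sets EB replicates 1, 2, 3, 4 and 6 apart), and in EC against EE 1 of 56 (real 3464, highest other 0). Among fragments, 1 of 30 splits reached the real count in each comparison: 60824 with a highest other of 46781 in EC against EB, 66910 with 0 in EE against EB, and 45810 with 0 in EC against EE. The split following EB replicates 1 to 3, not among the 30 drawn, called 162964 fragments, which again points to the structure of the EB libraries. Without those replicates EC against EB gave 72103 fragments.

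Single libraries of EB and EE were flagged as apart from their group in 14 of 372 tests of named genes and of library measures, all 14 for genes. EC, with 3 libraries, was not tested. Chance alone flags about 5% of groups whose libraries scatter as 1 set. The subsets of EB do not, and their gap can hide a library that stands apart. The flags number no more than that rate, but this does not show that no library stands apart. In EB replicate 7 Cyp309a1 had a signal of 1.773, with the others at 0.542 to 0.958. EB replicate 4 was low for Mhc (0.8354, others 1.21 to 1.45), Rim (0.4234, others 0.630 to 0.762), Tk (0.4931, others 0.839 to 1.17) and vnd (1.628, others 3.22 to 4.69). EE replicate 4 was high for AstA (4.465, others 2.58 to 2.74), E(spl)mdelta-HLH (8.129, others 5.44 to 6.11) and Nil (3.111, others 1.40 to 1.78) and low for loco (3.746, others 4.28 to 4.44). EE replicate 5 was low for GV1 (0.5287, others 0.669 to 0.682) and high for Phae2 (1.207, others 0.763 to 0.862). EE replicate 2 was high for Osi15 (1.342, others 0.826 to 0.915) and eya (2.366, others 1.60 to 1.72) and low for RpS28b (1.934, others 2.92 to 3.18). Fragments of the Y chromosome, outside the comparisons, had a mean signal with a median of 0.00496 over the 15 libraries (0.00220 to 0.00709). The large arms had means of 2.50 to 2.89, so the Y signal was close to none. It lay above the limit that 3 units of coverage over all Y fragments set in each library. That limit is low, and passing it does not show that the flies carried a Y chromosome.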

How the results depend on the processing

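The length-adjusted signal, the fits without EB replicates 1 to 3 and the wider or end windows around genes were chosen after the data were seen; the other alternatives were planned. Windows of 1 kb or 500 bp around the 5′ end were not run, since the gene table gives no strand. Except where a reason is given, the cause was not tested.

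Over all alternatives, 159 counts of called genes or fragments stayed within 1.5 times the reported count and 51 moved more. Values as deposited gave 4165, 2939 and 3467 genes in EC against EB, EE against EB and EC against EE, and both pseudocounts, no filter and limma without trend and robust also stayed within 1.5 times. Quantile normalization gave 1824 genes and 24927 fragments in EC against EE, equal medians 25277 fragments and centring on 100 kb windows 18167. With fewer features tested, a filter at the genome-wide median gave 1871, 1577 and 1000 genes and 27160 fragments in EC against EE, and the majority among genes turned over: 1008 higher and 863 lower, 627 and 950, and 585 and 415. Stricter thresholds gave, by construction, fewer calls: 2202, 899 and 1648 genes at a fold change of at least 2, and 2369, 1410 and 1967 genes and 24515, 26882 and 17647 fragments at an adjusted p under 0.01.

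With only the 2 groups compared in the fit, EC against EB gave 2728 genes and 27406 fragments, and EC against EE, which no longer shared the spread of the EB libraries, 5663 genes and 111022 fragments. Array weights gave 6610 genes and 132407 fragments in EC against EE and 100990 fragments in EC against EB. The run code as a random block gave 78810 fragments in EC against EE. With EB represented by replicate 7 alone, assumed to vary like the other groups, EC against EB gave 2021 genes and 22915 fragments and EE against EB 360 genes and 3813 fragments.

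The length-adjusted signal gave 5022 genes in EE against EB, and 6103 genes and 70078 fragments in EC against EE. Without EB replicates 1 to 3, EC against EE gave 5529 genes and 94626 fragments. Both together gave 6394, 4629 and 7414 genes, and 110358 fragments in EC against EE.

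The replicate number as a block gave 7086 and 5998 genes, and 145518 and 141673 fragments, in EC against EB and EE against EB, and in EE against EB most called genes were then lower (2285 higher and 3713 lower). Numbers did not pair the libraries: deviations of same-numbered libraries correlated at -0.38 to 0.45, and 3 of 15 libraries correlated best with their own number.

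Leaving out 1 library at a time gave 2595 to 4692, 2024 to 3769 and 2266 to 3707 genes, of which 2556, 2014 and 2199 at the lowest were also called with all libraries, and 23414 to 81531, 43466 to 92345 and 20144 to 50409 fragments. Counts moved by over 1.5 times without EC replicate 2 (2646 genes and 24681 fragments in EC against EB, 24518 fragments in EC against EE), EC replicate 3 (2595 and 2266 genes, 23414 and 20144 fragments), EC replicate 1 (28920 fragments in EC against EE) and EE replicate 2 (43466 fragments in EE against EB).

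Of 29 called list shifts, 2 held with an estimated correlation, be the signal length-adjusted or not, and 15 with centring on 100 kb windows. The estimated correlation drew on the spread of all libraries, the difference between the EB subsets included. Centring removes by construction the common shift of members that share a window. With the preset correlation the length-adjusted signal kept 27 of the 29. It ended the calls of stem cell and EB genes and of cell cycle genes in EC against EB, and EE hormones, neuronal genes and the Notch target complex passed in EE against EB. Over all alternatives, list shifts kept direction and call 266 times, lost the call 85 times, gained it 5 times and reversed 1 time: homeobox and patterning genes in EC against EE had a median log2 fold change of 0.051 with quantile normalization. The correlation of the EC and EE shifts was 0.484 and 0.448 with the EB libraries split and 0.447 with the length-adjusted signal.

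Named genes kept direction and call 8955 times, lost the call 431 times, gained it 158 times and reversed 28 times. Quantile normalization put gcm2 in EC against EE at 0.0022. Centring put, in EC against EB, Npc1b at -0.36, CCHa1 at 0.11, unc-13 at 0.018, sc at 0.064, Shaw at 0.41, knrl at 0.0015 and pros at 0.096, in EE against EB, Npc1b at -0.23, pros at -0.50, kni at 0.12 and RpL15 at 0, and in EC against EE pros at 0.60 and ind at 0.37. Centring subtracts a window median that includes the gene, so values such as those of knrl and RpL15 are partly fixed by the method. EB replicate 7 alone put ple in EE against EB at 0.0075. Gene bodies with 1 kb each side put PGRP-SC2 at -0.017 and -0.26 against EB in EC and EE, and DptB in EE against EB at -0.20. Windows around both gene ends put, in EC against EB, ITP at 0.38, loco at 0.81, Myo31DF at -0.037 and Mhc at 0.63, in EE against EB, Sytbeta at -0.35, pros at -0.28, PGRP-SC2 at -0.042 and DptB at -0.083, and in EC against EE, how at 0.0073 and Mhc at 0.16.

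At the depth and spread of these libraries, 39% of genes and 3% of fragments simulated with a log2 change of 1 were recovered. These shares are for EC against EB, with 200 changed features. The real comparison called 4163 genes and 60824 fragments, and the Benjamini-Hochberg cutoff is less strict where more features change. The shares are therefore not the recovery in the real data, which was not tested. Uncalled fragments are not read as evidence of no change.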

Other observations

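The gene families here were chosen by symbol after the data were seen, and all were tested with the same model as the lists. UDP-glycosyltransferase genes, which conjugate sugars to small molecules, were higher in EC than in EB: 17 higher and 3 lower of 33, with a median shift less that of all genes of 1.04 (adjusted p = 3.48e-06, and 0.0675 with an estimated correlation). Ugt37A2 stood at a signal of 11.9 ± 1.44 in EC (SD, n = 3) and 1.32 ± 0.658 in EB (n = 7), a log2 fold change of 2.84 ± 0.28 (SE), and Ugt37B1 changed by 2.34 ± 0.21. The family's shift was 0.77 with quantile normalization and 0.54 with centring on 100 kb windows. In EC against EE it was 0.85, with 15 higher and 3 lower (adjusted p = 4.93e-06, and 0.0675 with an estimated correlation). Cytochrome P450 genes gave 26 higher and 10 lower of 82 in EC against EB (0.43, adjusted p = 6.41e-04, and 0.109 with an estimated correlation), with Cyp12d1-p at 2.50 ± 0.19 and Cyp304a1 at 2.43 ± 0.24, and proteasome genes gave 10 higher and 3 lower of 44 (0.51, adjusted p = 0.00349, and 0.183 with an estimated correlation), with Rpn7 at 1.36 ± 0.23.

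Gustatory receptor genes were higher in EE than in EB, with 16 higher and 0 lower of 50 (0.39, adjusted p = 9.26e-05, and 0.195 with an estimated correlation), and lower in EC than in EE (1 higher and 24 lower, -0.68, adjusted p = 1.21e-05, and 0.195 with an estimated correlation). Gr9a changed by 1.32 ± 0.19 and Gr47b by 1.29 ± 0.21 in EE against EB. The shift in EE against EB was 0.32 with quantile normalization and 0.21 with centring, and that in EC against EE -0.31 and -0.51. Odorant receptor genes were lower in EC than in EE, with 0 higher and 25 lower of 44 (-0.65, adjusted p = 1.51e-06, and 0.109 with an estimated correlation), with Or63a at -1.84 ± 0.20, and their shift was -0.28 with quantile normalization and -0.42 with centring. Osiris genes were lower in EC than in EB, with 1 higher and 18 lower of 24 (-0.71, adjusted p = 4.00e-04, and 0.195 with an estimated correlation), and their shift was 0.08 with centring on 100 kb windows. Centring removes by construction the shift of members that share a window, so 0.08 does not show that the shift is regional.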
